A study of Mus musculus with 4 samples.

How the data were processed

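Gene expression was measured on 4 Affymetrix MG_U74Av2 arrays, 1 from R1 ES cells and 3 from XEN cell cultures (IM8A1-I, IM8A1-II and XEN1-3, called XEN replicates 1, 2 and 3). Groups were taken from the labels. The XEN cultures represent 2 lines, and 2 of the 3 are the same line under different conditions. The p-values of single probe sets therefore measure the spread between these cultures, and the single ES culture is assumed to vary in the same way. The deposited values are intensity summaries on a linear scale, 1 per probe set and array, for 12488 probe sets. The software that summarised the probes is not given in the sources used here. The 2% trimmed means of the deposited values (150.092, 150.095, 150.09 and 150.088) show that the arrays had already been scaled to a common level. No text in the sources used here describes that step.

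Run records deposited with the arrays were read for the chip type, chip lot and fluidics messages. Per the file headers, the ES array came from chip lot 1 and the 3 XEN arrays from lot 2 (lots are numbered here in order of appearance) and they were run on different days, so that batch and group cannot be told apart and no fit with batch as a term was possible. The record of XEN1-3 carries a fluidics message that no fluid was detected and gives no wash and stain settings, and the record of IM8A1-II describes its sample with the letters DIFF, which the labels do not explain. RNA quality, read as the ratio of 3' to 5' control probe sets, was alike: 1.25, 1.21, 1.24 and 1.21 for actin and 1.02, 0.969, 0.954 and 1.08 for Gapdh in ES, IM8A1-I, IM8A1-II and XEN1-3.

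Values were rescaled to a common 2% trimmed mean (a factor of 1.00 for each array), 10.5 units (the 25th percentile of all values) were added and log2 was taken. Fold changes on this scale understate the change of dim genes. The background limit was the 40th percentile of all values, 27.3 units, and all 76 values of 19 control probe sets of bacterial and yeast sequence lay under it, the highest at 19.6. It is not a detection call. A probe set was tested if at least 1 array reached the limit, which kept 8582. Where a group lay wholly under the limit, the fold is given as at least the geometric mean of the brighter group over the limit.

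Gene symbols came from the platform annotation supplied with the data. Of the 12488 probe sets, 66 were controls and 1237, some of them controls, had no symbol. Among the rest 10833 carried 1 symbol and 396 several, leaving out control probe sets with a symbol, which were not used. Of the 10833, 10817 were found by gene ID in the RefSeq gene table of assembly GRCm38.p6, with 0 symbols changed. That table also gave chromosomes. Its gene start positions were used only to order the genes of chromosomes 16 and 4. The probe sets themselves were not placed on a genome here. The probe set with the highest mean log2 value represented a gene in the lists and named values, giving 6351 genes, of which 1149 had at least 2 tested probe sets. Probe sets with several symbols were left out of the lists. List members under the limit on all arrays were not tested, and the counts, medians and measured members of lists leave them out. In the BMP, TGF-beta and Nodal list, for example, 21 of 30 genes on the array were tested.

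XEN and ES were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 2 residual degrees of freedom and a prior of 3.76), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The 24 gene lists, fixed before the data were examined along with the tests, the naming rule and the alternatives, were tested with camera from limma at a preset correlation of 0.01, adjusted over the 24 lists, and with an estimated correlation. At the preset correlation camera sets the members of a list against the other genes of the same arrays. Its p-values then depend on the number of genes and do not measure the spread between cultures. The test with an estimated correlation draws on only the 2 residual degrees of freedom, so few lists can pass it. Some lists share members, for example 5 between the pluripotency list and the BMP, TGF-beta and Nodal list. IM8A1-II and XEN1-3 were each compared with IM8A1-I, array against array, without a test. A list's median was placed among 10000 random lists of the same size matched on mean expression, which describes these arrays and is no p-value. Figures were drawn with matplotlib 3.10.9.

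Genes were named by a fixed rule. For XEN against ES it took the 12 largest rises and the 12 largest falls among probe sets past the threshold that had 1 gene symbol, reached the 60th percentile of all values (84.7 units) on at least 1 array and lay at least 2-fold from ES in the same direction in all 3 XEN arrays. It also took up to 4 members of each list with the smallest p, and 9 lineage regulators in every comparison. Within XEN it took the 8 largest differences in each direction and up to 3 members of each list that stood apart. Exceptions are marked as named after their values were seen.

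The test was run on simulated arrays with 8582 probe sets, of which 200 were changed, 50 for each size. It recovered 0%, 28%, 52% and 82% of changes of 1, 2, 3 and 5 in log2, with 2 false calls, and made 0 calls when nothing was changed. All changes of 1 in log2 and most of 2 were thus missed in the simulation, and larger ones were missed in part. All 4 simulated arrays were drawn independently with the spread of the XEN arrays. The simulated ES array thus varied as assumed, without a chip lot effect, and no XEN arrays shared a line. The simulation cannot check these points. The data gave 912 calls, against 200 changed probe sets here, so the recovered shares need not carry over. The placement among random lists put 0 of 20 random lists outside the range and a list of 20 genes shifted by 0.5 at percentile 99.8. The alternatives were the deposited scale, quantile normalization, median scaling, other offsets, a floor at the limit, no filter or a stricter one, no variance trend, each XEN line counted once, each XEN array left out in turn, an estimated correlation, the mean of a gene's probe sets and a 3-fold limit. No values of other series were in the table.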

Results

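The series set mouse embryonic stem (ES) cells, pluripotent cells derived from the inner cell mass, against extraembryonic endoderm (XEN) cells, stem-like lines of the lineage that forms the parietal and visceral endoderm of the yolk sacs. Total RNA from 4 cultures was measured on 4 Affymetrix MG_U74Av2 arrays, 1 array per culture. The ES group was 1 culture of undifferentiated R1 cells grown on gelatin with LIF. The XEN group was 3 cultures. IM8A1-I and IM8A1-II came from the IM8A1 line (PO strain) at passage 27, the former on gelatin in medium labelled 70% EMFI-CM and the latter for 4 days on tissue culture plastic in RPMI 1640 with 20% fetal bovine serum. XEN1-3 (ICR strain) was at passage 18 and, like IM8A1-I, was on gelatin in 70% EMFI-CM. Signal is in arbitrary units. The median over all probe sets was 46.7 in ES, 48.8 in IM8A1-I, 52.2 in IM8A1-II and 49.9 in XEN1-3, and 59.7%, 59.6%, 60.5% and 60.2% of the probe sets lay at or above the background limit of 27.3 units.

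The 3 XEN arrays resembled each other far more than any of them resembled ES. Across 8582 probe sets, Pearson's r of the log2 signals was 0.954 between the IM8A1 cultures, 0.930 between IM8A1-I and XEN1-3, and 0.928 between IM8A1-II and XEN1-3. Against ES it was 0.773 for IM8A1-I, 0.775 for IM8A1-II and 0.784 for XEN1-3. These are correlations across genes, which are not independent replicates. At least 2-fold differences were seen for 28.4%, 27.7% and 27.0% of the probe sets between ES and IM8A1-I, IM8A1-II and XEN1-3, compared with 5.98% between the IM8A1 cultures, 9.11% between IM8A1-I and XEN1-3 and 9.53% between IM8A1-II and XEN1-3.

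The main comparison asked which transcripts separate XEN from ES cells. Pou5f1, Sox2 and Nanog, transcription factors that maintain pluripotency, were abundant in ES cells and under the background limit in all 3 XEN arrays. Pou5f1 (Oct4) stood at 3191 units in ES and 2.17 ± 0.404 in XEN (SD, n = 3), at least 117-fold lower, Sox2 at 3391 and 4.47 ± 3.27, at least 124-fold lower, and Nanog at 3275 and 19.2 ± 3.60, at least 120-fold lower. In the other direction, the endoderm transcription factors Gata6 and Sox17 were under the limit in ES and bright in XEN, with Gata6 at 13.1 against 1842 ± 700.1 (at least 63.8-fold higher) and Sox17 at 13.9 against 1633 ± 309 (at least 59.1-fold higher). Gata4, a partner of Gata6 in endoderm, went from 40.9 to 1062 ± 151, a rise of 4.37 ± 0.29 on the log2 scale (SE, limma adjusted p = 0.00220), and Foxa2 from 7.70 to 528 ± 20.9, at least 19.3-fold higher.

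In limma's moderated test 479 probe sets rose and 433 fell in XEN at an adjusted p under 0.05, out of 8582 tested, representing 397 and 358 genes. All 479 rises and 432 of the 433 falls were at least 2-fold in each of the 3 XEN arrays. The counts depended on single arrays: 185 rose and 181 fell without IM8A1-I, 233 and 211 without IM8A1-II, and 778 and 710 without XEN1-3. Which direction had more calls depended on the processing. With values raised to the background limit 240 rose and 536 fell. The counts were 394 and 531 with an offset of the 50th percentile, 428 and 508 with median scaling, 437 and 450 without a variance trend, and 323 and 391 without a filter. There was 1 ES array, on a different chip lot from the XEN arrays, so chip lot and cell type cannot be told apart, and the ES culture is assumed to vary as the XEN cultures do.

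**Figure D1:**
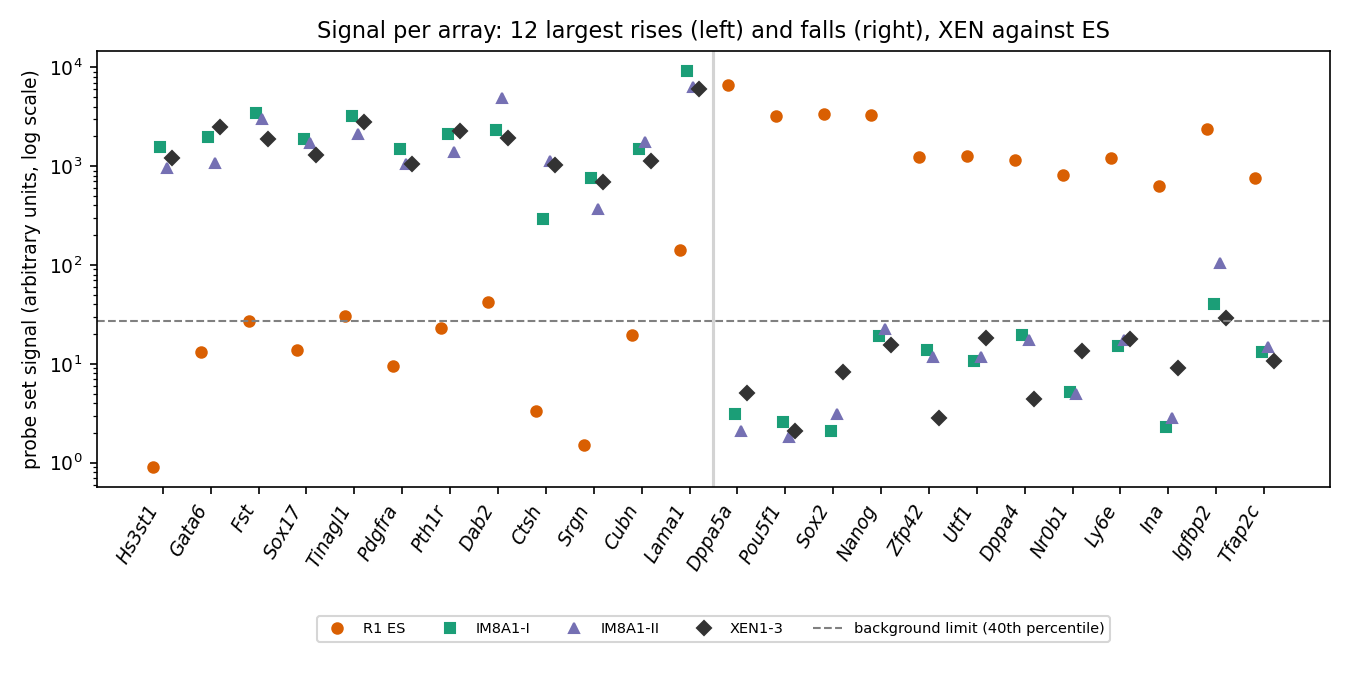
Probe set signal in arbitrary units (log axis) on each of the 4 arrays, 1 point per array, for the 12 genes with the largest rise and the 12 with the largest fall in XEN against ES. The dashed line is the background limit of 27.3 units. Pou5f1 stands at 3191 units in ES and 2.17 on average in XEN, and Gata6 at 13.1 in ES and 1842 on average in XEN.

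Among the 12 largest rises, basement membrane and secreted products stood beside the regulators. Lama1, the laminin alpha chain of the embryonic basement membrane, rose from 142 to 7233 ± 1761 units, or 5.54 ± 0.33 in log2. Tinagl1, a matrix glycoprotein, rose by 6.03 ± 0.32, from 30.3 to 2696 ± 544, and the endocytic adaptor Dab2 by 5.74 ± 0.54, from 42.4 to 3065 ± 1634. The other members were under the limit in ES: Fst, the activin antagonist follistatin (at least 98.5-fold higher), Pth1r, the parathyroid hormone-related peptide receptor (69.1-fold), Cubn, the scavenging receptor cubilin (52.3-fold), the heparan sulfate sulfotransferase Hs3st1 (44.6-fold), the growth factor receptor Pdgfra (43.4-fold), the cathepsin Ctsh (25.5-fold) and the proteoglycan Srgn (21.2-fold). Ctsh did not pass with values raised to the limit (adjusted p = 0.110). A further, dim probe set each for Gata6, Pdgfra and Cubn did not show these rises, with log2 changes of 0.22, 0.52 and -0.18, none past the threshold.

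The pluripotency list had 32 measured members, of which 23 fell, 1 rose and 8 did not pass the test. Adjusted over the list alone, 25 fell and 2 rose. Its median log2 change was -2.92, or -2.72 with the 15 members that were under the limit in a whole group set at their bounds (camera adjusted p = 0.202 with an estimated correlation). Dppa5a fell from 6642 to 3.43 ± 1.53 units, at least 243-fold, and Zfp42 (Rex1), Utf1, Dppa4 and Nr0b1 were at least 45.1-fold, 46.3-fold, 41.9-fold and 30.1-fold lower. The member that rose was Kit, a receptor tyrosine kinase, from 243 to 1132 ± 267, named here after its values were seen. Outside the list, the largest falls included the neuronal intermediate filament gene Ina (at least 23.2-fold), the surface antigen gene Ly6e (at least 44.8-fold), Tfap2c (at least 28.1-fold) and Igfbp2, from 2364 to 57.5 ± 40.4 (not past the threshold with values raised to the limit, adjusted p = 0.0740). A second, dim probe set of Pou5f1 and of Ly6e stayed near the limit on all arrays, with log2 changes of -0.19 and -0.15.

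Of 16 measured extraembryonic endoderm regulators, 12 rose, 0 fell and 4 did not pass, and 13 rose when adjusted over the list alone. The median was 4.27 in log2, and 3.85 with 10 members at their bounds (camera adjusted p = 0.202 with an estimated correlation). Foxq1, a forkhead factor, stood at 10.3 in ES and 342 ± 19.4 in XEN. Sox7 had an adjusted p of 0.0448 and uneven XEN levels of 1339, 225 and 981 units in IM8A1-I, IM8A1-II and XEN1-3. Its adjusted p was 0.0811 without IM8A1-I, 0.153 with values raised to the limit, 0.0775 without a filter and 0.0708 with an offset of the 50th percentile. Hnf4a, a visceral endoderm regulator, was dim, at 3.70 in ES and 19.6 ± 15.9 in XEN, a log2 difference of 0.95 ± 0.65 that did not pass (adjusted p = 0.375).

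Of 24 parietal endoderm and basement membrane genes 15 rose, 1 fell and 8 did not pass (17 and 3 adjusted over the list alone). The median was 2.58, the same with 5 members at their bounds (camera adjusted p = 0.358 with an estimated correlation). The coagulation initiator F3 (tissue factor) went from 75.6 to 3295 ± 577 and the collagen chaperone Serpinh1 from 221 to 4432 ± 361 units. The member that fell was Col18a1, a basement membrane collagen, by 3.67 in log2 from 695 to 45.6 ± 10.5, and it was named after its values were seen. Of 28 visceral endoderm genes on the array, 19 were tested, and the rest lay under the limit on all arrays. Among the 19, 3 rose, 0 fell and 16 did not pass (5 rose adjusted over the list alone). The 3 were Cubn, the endocytic receptor Lrp2 (113 to 341 ± 75.2, adjusted p = 0.0477) and the Wnt antagonist Dkk1 (adjusted p = 0.0477). Without IM8A1-I the adjusted p of Lrp2 and Dkk1 was 0.108 and 0.0896, without IM8A1-II 0.0664 and 0.0780, with values raised to the limit 0.0997 and 0.325. Both also missed the threshold with each XEN line counted once, with median or quantile scaling, with an offset of the 50th percentile and without a filter. The visceral median was 1.48, but 0.47 with the 11 members under the limit in a whole group set at their bounds (camera adjusted p = 0.538 with an estimated correlation). Without a filter on dim probe sets the median was 0.28.

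Some genes of the secretory and degradative compartments rose, in lists that did not pass with an estimated correlation (camera adjusted p of 0.202 and 0.358). In the secretory pathway and collagen processing list 8 of 18 members rose and 0 fell (13 rose adjusted over the list alone; median 1.13), among them the collagen prolyl hydroxylase subunits P4ha1, from 170 to 1788 ± 27.8, and P4ha2, from 163 to 2651 ± 809. In the lysosome list 11 of 20 rose and 1, the beta-glucuronidase gene Gusb, fell (15 and 1 adjusted over the list alone; median 1.38, the same with 4 members at their bounds). The asparaginyl protease Lgmn rose from 115 to 2768 ± 963 units and Ctsl from 704 to 4047 ± 1042 (adjusted p = 0.0606 with values raised to the limit). Gusb was lost as a call without IM8A1-I (adjusted p = 0.103) or IM8A1-II (0.0639), with each XEN line counted once (0.0522), without a filter (0.0618) and with an offset of the 5th percentile (0.0579).

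The proliferation list had a median of -0.51 (camera adjusted p = 0.358 with an estimated correlation). Of its 21 members 2 fell and 19 did not pass (2 also adjusted over the list alone): the mitotic activator Cdc20, from 1858 to 679 ± 126, and cyclin E1 (Ccne1), from 525 to 220.3 ± 7.32. Neither passed without IM8A1-I (adjusted p of 0.0773 and 0.110), without IM8A1-II (0.0861 and 0.104) or with each XEN line counted once (0.0585 and 0.0799). Cdc20 also did not pass with values raised to the limit (0.0869) or without a filter (0.0589). Of 15 epithelial junction genes 5 fell, 0 rose and 10 did not pass (6 fell adjusted over the list alone; median -0.88, the same with 5 members at their bounds). This list's camera adjusted p was 0.526 with an estimated correlation, and its median over ES was -0.95 in IM8A1-I, -0.03 in IM8A1-II and -1.25 in XEN1-3. Spint1, a membrane protease inhibitor, went from 245 to 8.20 ± 5.33, claudin genes Cldn4 from 350 to 17.6 ± 10 and Cldn7 from 114 to 1.40 ± 0.529, and the adhesion molecule Epcam from 151 to 23.2 ± 7.64. In the amino acid and endoplasmic reticulum stress list (median 0.88, camera adjusted p = 0.665 with an estimated correlation) 2 of 17 members rose and 15 did not pass (4 rose adjusted over the list alone). These were Xbp1, a factor of the unfolded protein response, at 200.3 in ES and 873 ± 78.1 in XEN, and the tryptophanyl-tRNA synthetase Wars, at 379 and 1703 ± 308, whose other probe sets rose without passing (adjusted p of 0.0798 and 0.0803). The median of this list over ES was 1.80 in IM8A1-I, 0.49 in IM8A1-II and 0.45 in XEN1-3.

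Set tests with camera at a preset inter-gene correlation of 0.01 called 9 of the 24 lists. They were pluripotency (adjusted p = 7.78e-16), extraembryonic endoderm regulators (5.94e-11), parietal endoderm (5.79e-09), secretory pathway (7.25e-08), lysosome (1.48e-06), proliferation (0.00193), stress (0.00573), visceral endoderm (0.00931) and epithelial junction (0.0142). These p-values set members against the other genes of the same arrays and do not measure the spread between cultures. With an estimated correlation 0 of the 24 lists passed (3 at an unadjusted p under 0.05). That test draws on only the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. The estimated correlation of the pluripotency, extraembryonic endoderm regulator, secretory and proliferation lists (0.0023, -0.015, -0.010 and -0.030) lay below the preset 0.01. By these estimates, correlation between members would not account for the loss of these calls. The estimate lay above the preset value in the stress, visceral, parietal, lysosome and epithelial junction lists (0.54, 0.19, 0.14, 0.12 and 0.086). For these lists the preset value may understate the correlation and make p too small. All estimates rest on the same 2 residual degrees of freedom, so low ones cannot exclude correlation either. The visceral list was not called without a filter on dim probe sets (adjusted p = 0.0797) or with values raised to the background limit (0.168).

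**Figure D2:**
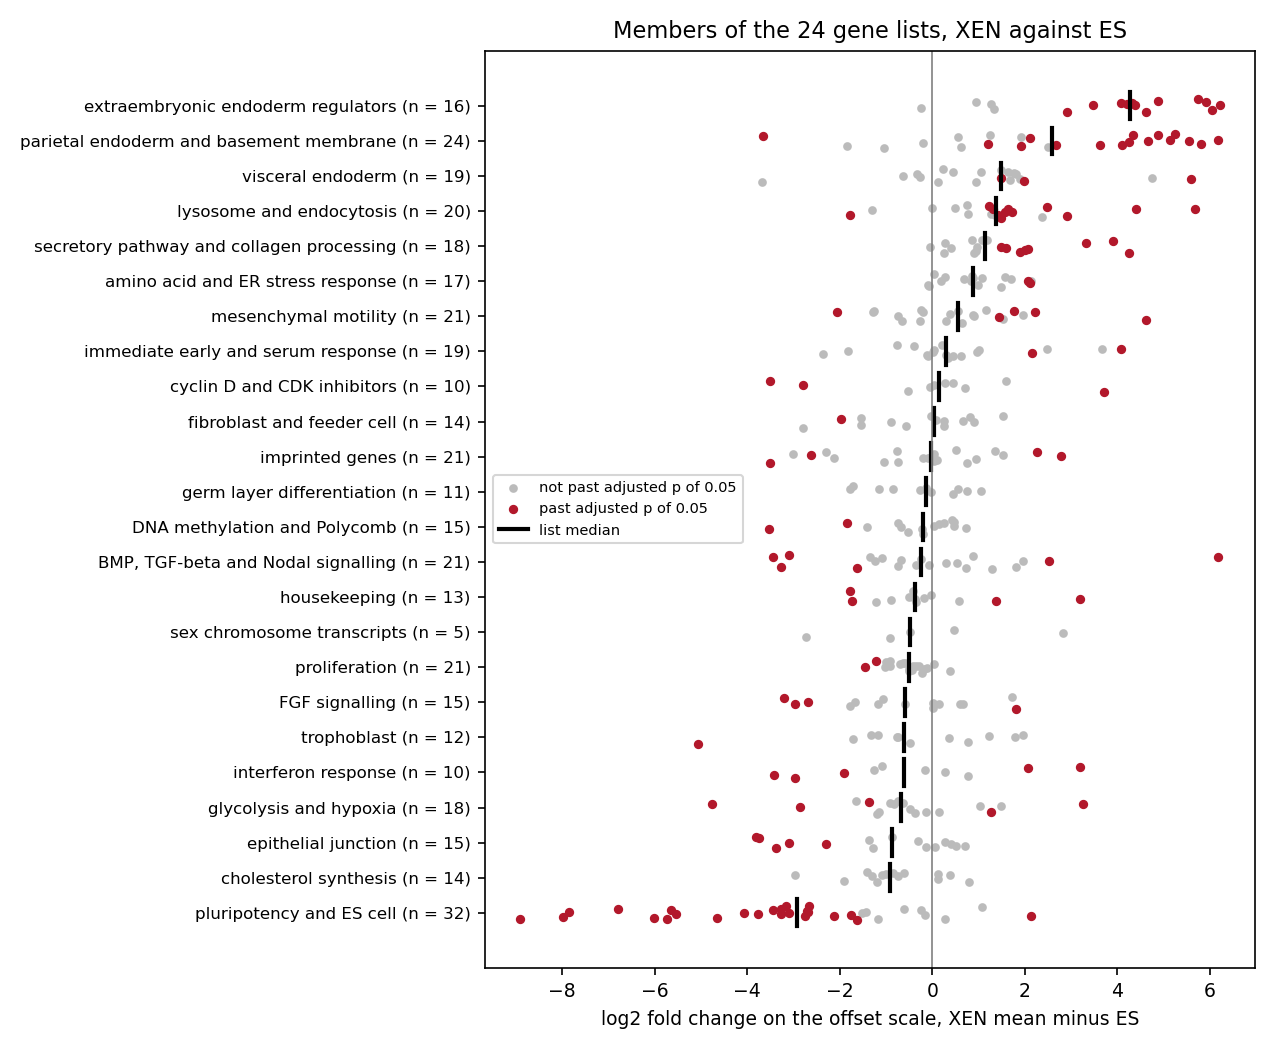
Log2 fold change (XEN mean minus ES, on the offset scale) of each measured member of the 24 gene lists, 1 point per gene, red where the adjusted p was under 0.05, with a black bar at the list median. The medians run from -2.92 for pluripotency to 4.27 for extraembryonic endoderm regulators.

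Lists of other cell types the cultures could hold showed no call. Members under the limit on all arrays were not tested. This left 14 of 21 fibroblast, 12 of 16 trophoblast and 11 of 20 germ layer genes on the array. In the fibroblast list Tagln stood at 538 in ES and 37.7, 214 and 36.1 in IM8A1-I, IM8A1-II and XEN1-3. It did not pass in the main test but passed as lower under some alternatives. Among 14 fibroblast and feeder cell genes 1 fell, Thy1, from 48.5 to 4.47 ± 1.40 (1 also adjusted over the list alone), and the collagen gene Col1a2 stood at 206 and 369 ± 28.9 without passing (camera adjusted p = 0.620). Thy1 did not pass without IM8A1-I (adjusted p = 0.0973) or IM8A1-II (0.0883), with each XEN line counted once (0.0651) or with an offset of the 5th percentile (0.0787). Of 12 trophoblast genes 1, Tfap2c, fell, while Eomes, a trophoblast and mesendoderm factor, was dim at 32.6 and 2.60 ± 0.265 (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.342). None of 11 germ layer genes passed limma's test over all probe sets, with Fgf8 at 32.3 and 1.97 ± 0.416, against 2 that fell adjusted over the list alone, and 1 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.549). Fgf8 and Eomes passed as lower without a filter (adjusted p of 0.0126 and 0.0140), with values raised to the limit (0.0213 and 0.0193), without a variance trend (0.0205 and 0.0221) and with an offset of the 50th percentile (0.0386 and 0.0410). So did the embryonic globin gene Hbb-bh1 (0.00231) and the fibroblast list's Prrx2 (0.00252) with values raised to the limit. Sex chromosome transcripts had 0 calls among 5 in limma's test, also adjusted over the list alone, and 1, Kdm6a, lower at an unadjusted p under 0.05 (camera adjusted p = 0.549). Without XEN1-3, which leaves only cultures of the IM8A1 line, the X-inactivation transcript Xist differed from ES by 4.14 in log2 and the Y-linked Eif2s3y by -3.75. In XEN1-3 these genes stood at 4.80 and 145 units, so these differences belong to the IM8A1 line and not to XEN cells as a group.

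Several signalling and cell cycle genes changed in lists that as a whole were not called in the main test, though some alternatives called the FGF and the DNA methylation and Polycomb lists. In the FGF list 3 of 15 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0741): the ES cell growth factor Fgf4, from 1056 to 156 ± 17.6, Fgf17, from 123 to 4.03 ± 1.5, and the receptor Fgfr1, from 206 to 18.2 ± 9.15, against the receptor Fgfr4, from 3.50 to 38.3 ± 3.12. At the preset correlation the FGF list passed without a filter (adjusted p = 0.0412) and with values raised to the background limit (0.0421). With an estimated correlation its adjusted p was 0.526. Fgfr4 did not pass without IM8A1-I (adjusted p = 0.0941) or IM8A1-II (0.0745), with each XEN line counted once (0.0565) or with values raised to the limit (0.126). In the BMP, TGF-beta and Nodal list 4 of 21 fell and 2 rose (5 and 4 adjusted over the list alone; camera adjusted p = 0.818), with Nodal at 245 and 16.3 ± 3.99 and its antagonist Lefty1 at 524 and 52.2 ± 3.51, against rises of Fst and of the receptor Acvr1, from 4.00 to 74.0 ± 16.3 (adjusted p = 0.103 with values raised to the limit). Among the D-type cyclins, Ccnd2 rose from 8.40 to 252 ± 98 and Ccnd1 fell from 279 to 32.6 ± 12.3 (another probe set fell by 1.51 in log2 without passing), while the CDK inhibitor Cdkn1c fell from 232 to 10.8 ± 2.21 (1 rise and 2 falls in 10 members, also adjusted over the list alone; camera adjusted p = 0.981). With values raised to the limit, neither Ccnd2 (adjusted p = 0.0852) nor Ccnd1 (0.0560) passed. Among 15 DNA methylation and Polycomb genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.203, 0.0190 with a stricter filter on dim probe sets and 0.534 with an estimated correlation). They were Jarid2, from 2732 to 230.3 ± 54.8, and Eed, from 768 to 208 ± 19.5, which did not pass without IM8A1-I (adjusted p = 0.0592) or IM8A1-II (0.0513).

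The mesenchymal motility list had 4 rises and 1 fall among 21 members (6 and 3 adjusted over the list alone; camera adjusted p = 0.197). Snai1, a repressor of epithelial genes, stood at 8.40 in ES and 496 ± 226 in XEN, and the urokinase receptor Plaur rose from 43.2 to 240 ± 5.62. Snai1 did not pass with values raised to the limit (adjusted p = 0.0898). The integrin genes Itga5 and Itgav rose by 1.77 ± 0.28 and 1.44 ± 0.28 in log2. Without IM8A1-I the rises were 1.69 and 1.54 but did not pass (adjusted p of 0.0643 and 0.0736). Without IM8A1-II they were 1.81 and 1.34, again without passing (0.0558 and 0.0714). Itgav also did not pass with values raised to the limit (0.0602). Of 21 imprinted genes 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.829), namely Sgce, from 96.6 to 750.0 ± 243, and Plagl1, from 17.4 to 128 ± 42.8, against Cdkn1c and Igf2, from 681 to 112 ± 69.4. Plagl1 did not pass without IM8A1-I (adjusted p = 0.0793) or without a filter (0.0565). Igf2 did not pass without IM8A1-I (0.0969), IM8A1-II (0.0862) or a filter (0.0742) or with each XEN line counted once (0.0733). With values raised to the limit, Sgce (0.0662), Plagl1 (0.119) and Igf2 (0.153) missed the threshold. Immediate early and serum response genes had 2 rises and 0 falls among 19 (5 and 1 adjusted over the list alone; camera adjusted p = 0.203), the matricellular factor Ccn2, from 251 to 4743 ± 2190, and Tgfb1i1, from 88.3 to 441 ± 113, which did not pass without IM8A1-I (adjusted p = 0.0654). Neither passed with values raised to the limit (0.0722 and 0.0730). Atf3, from 51.2 to 958 ± 635, passed only under some alternatives. Another probe set for it passed the main test as higher, by 2.81 in log2.

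In the interferon list 10 of 20 genes on the array were tested. Of these, 3 fell and 2 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.342). The transcription factor Irf1 fell from 220.5 to 12.3 ± 9.06 and the immunoproteasome subunit Psmb8 from 105 to 4.6 ± 2.86, whereas the MHC class I light chain B2m rose from 192 to 1878 ± 368. Isg15 fell from 61.0 to 8.5 ± 1.71, but did not pass without IM8A1-I (adjusted p = 0.0824) or IM8A1-II (0.0799), with each XEN line counted once (0.0541) or with an offset of the 5th percentile (0.0555). Of 18 glycolysis and hypoxia genes 3 fell and 2 rose (7 and 4 adjusted over the list alone). The phosphofructokinase Pfkp fell from 437 to 6.90 ± 7.31 and the pyruvate dehydrogenase kinase Pdk1 from 756 to 96.2 ± 22.2, while Ndrg1 rose from 144 to 1478 ± 261. Aldoa fell from 4502 to 1726 ± 69.4, and did not pass without IM8A1-I (adjusted p = 0.0861). The glycolysis list had a camera adjusted p of 0.0505, and 0.507 with an estimated correlation. At the preset correlation it passed without IM8A1-II (0.0253), with the stricter filter (0.0268), with each XEN line counted once (0.0362), with an offset of the 50th percentile (0.0461) and without a filter (0.0496). None of 14 cholesterol synthesis genes passed limma's test, over all probe sets or over the list alone, and 1 was lower at an unadjusted p under 0.05, with a median of -0.92 (camera adjusted p = 0.151). At the preset correlation this list passed without IM8A1-II (adjusted p = 0.0372), without XEN1-3 (0.0471) or with each XEN line counted once (0.0399). With an estimated correlation its adjusted p was 0.734. Idi1, an isomerase of the pathway, stood at 952 in ES and 145 ± 103 in XEN, and passed without IM8A1-I (adjusted p = 0.0459) and with each XEN line counted once (0.0315).

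Housekeeping genes, 13 in number, had 2 rises, B2m and Actb, and 2 falls, Hprt and Gusb (2 and 4 adjusted over the list alone; camera adjusted p = 0.253). Hprt fell from 1420.2 to 424 ± 71.5, a call lost without IM8A1-I (adjusted p = 0.0749) or IM8A1-II (0.0575) and with values raised to the limit (0.0603). Actb, at 301 and 805 ± 149, had an adjusted p of 0.0497, and missed the threshold under 9 alternatives (0.0517 to 0.131). Its other probe set gave 0.67 in log2 without passing.

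The pair IM8A1-II and IM8A1-I set the same line and passage in different culture conditions side by side, with 1 array each, so the differences have no replicate check and no test. The run record of IM8A1-II describes its sample with the letters DIFF, which the labels do not explain. Whether the 2 cultures differed only in the labelled conditions is therefore not known. On the IM8A1-II array, visceral endoderm and cholesterol synthesis genes stood higher than on the IM8A1-I array. The retinol carrier Rbp4 stood at 2671 units in IM8A1-II and 171 in IM8A1-I, 3.88 higher in log2, and the apolipoprotein Apoe at 888 and 138, 2.60 higher. The stress transcription factor Ddit3 (CHOP) was lower, at 206 and 1512, as was the endoderm factor Sox7, at 225 and 1339. Gata4, Gata6, Sox17 and Foxa2 were within 2-fold of each other in the 2 cultures, at 899 and 1196, 1086 and 1973, 1712 and 1895, and 520.1 and 512 units, and Foxa2 changed sign with median scaling (0.02 to -0.07).

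At least 2-fold differences were counted for 301 probe sets higher and 212 lower in IM8A1-II, and at least 3-fold for 80 and 40. Counts at 2-fold ranged widely with the offset, from 108 higher and 64 lower with a large offset (the 50th percentile) to 465 and 360 with a small one (the 5th). The largest differences upward, besides Rbp4 and Apoe, were in Emb, an immunoglobulin superfamily protein (1036 and 63.0), Mybpc3, a cardiac myosin-binding protein (647 and 53.2), the BMP target Id3 (at least 5.45-fold), Plet1 (at least 5.05-fold), and the sterol enzymes Msmo1 (326 and 43.3) and Fdps (819 and 125, though a dim probe set for it was 0.79 lower in log2). Downward they were in Nupr1, a stress-induced regulator (38.1 and 475), Fgf3 (at least 3.74-fold), Sphk1 (at least 4.35-fold), Bcat1 (139 and 1076), Cyb5r1 (127 and 682, but 157 and 278 in another probe set) and Atf5 (92.5 and 507).

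Of the 24 lists, 6 had a median outside the range of 10000 random lists matched on size and mean expression, with 2.5% of them left out at each end. All 14 cholesterol synthesis genes were higher in IM8A1-II than in IM8A1-I, with a median of 1.33, above all random lists drawn. Of 19 visceral endoderm genes 10 were at least 2-fold higher and 0 at least 2-fold lower (median 1.18, also above all random lists), including Apom (at least 1.94-fold). Epithelial junction genes had a median of 0.41 (percentile 99.8), with Cldn6 at 756 and 150.2, F11r at 1575 and 352, and Ocln at least 1.85-fold higher, and lysosome genes 0.31 (percentile 99.9), with Ctsh at 1131 and 291 and Lipa at 202 and 66.3, against Hexa, at least 2.28-fold lower. Stress genes had a median of -0.70 (below all random lists), with the amino acid transporter Slc7a5 at 642 and 2844 and Trib3 at 119 and 525, and parietal endoderm genes -0.29 (percentile 0.26), with Thbd at 199 and 393 (123 and 146 in another probe set) and Nid1 at 108 and 207, against Tfpi, higher at 1457 and 713.

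The pair XEN1-3 and IM8A1-I set different lines, from different strains and at different passages, side by side in the same medium and on the same substrate, again with 1 array each and no test. Some endoderm regulators were within 2-fold, with Gata4 at 1091 units in XEN1-3 and 1196 in IM8A1-I, Gata6 at 2468 and 1973, Sox7 at 981 and 1339, Sox17 at 1293 and 1895 and Foxa2 at 552 and 512. Large differences lay in other genes. Fabp3, a fatty acid-binding protein, was at least 91.4-fold lower in XEN1-3 (16.6 and 2497), Bcat1, a branched-chain aminotransferase, at least 39.4-fold lower (15.1 and 1076), and the X-linked homeobox gene Rhox5 was at 61.8 and 2045. Xist was under the limit in XEN1-3 and at 207 in IM8A1-I, at least 7.58-fold lower, whereas Eif2s3y was at 145 in XEN1-3 and under the limit in IM8A1-I, at least 5.29-fold higher.

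At least 2-fold differences numbered 393 higher and 389 lower in XEN1-3, and at least 3-fold 99 and 147. With an offset of the 50th percentile the 2-fold counts were 125 and 177. Further differences upward were Rsrp1 (at least 15.8-fold), Rps4l (710 and 32.7, though another probe set for it stayed near the limit at 28.1 and 18.0), Perp (at least 5.40-fold), the malic enzyme Me1 (1736 and 162), smooth muscle actin Acta2 (at least 5.98-fold), Mybpc3 (500.1 and 53.2) and the imprinted RNA Meg3 (at least 4.65-fold, though another probe set for it was near the limit at 29.3 in XEN1-3). Downward were Pea15a (at least 15.0-fold), the linker histone gene H1f2 (at least 9.32-fold), Mdfic (at least 8.12-fold) and the lipid droplet protein Plin2 (at least 10.8-fold).

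Of the 24 lists, 5 had medians outside the random range. Cholesterol synthesis genes were higher in XEN1-3 in 14 of 14 cases (median 1.39, above all random lists), with Msmo1 at 280 and 43.3, Fdps at 660.0 and 125 and Idi1 at 171 and 31.2. Stress genes had a median of -0.85 (below all random lists), with Trib3 at 60.3 and 525 and Ddit3 at 193 and 1512. Immediate early genes had a median of -0.51 (below all random lists), with Dusp1 at 54.0 and 360, Atf3 at 288 and 1551 (237 and 469 in another probe set) and Egr1 at 37.0 and 199. Parietal endoderm genes had a median of -0.41 (percentile 0.02), with the laminin chain Lamb1 at 2150 and 7056 (2929 and 4453 in another probe set), against Nid1, higher at 445 and 207. BMP, TGF-beta and Nodal genes had a median of -0.24 (percentile 1.59), with Smad2 at 208 and 520.5, but 10 of 21 were higher, Inhba at least 1.6-fold. Both pairs share the IM8A1-I array, so what is peculiar to that array enters both, and between XEN1-3 and IM8A1-II the medians of the stress and cholesterol lists were 0.02 and -0.14, inside the random range.

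**Figure D3:**
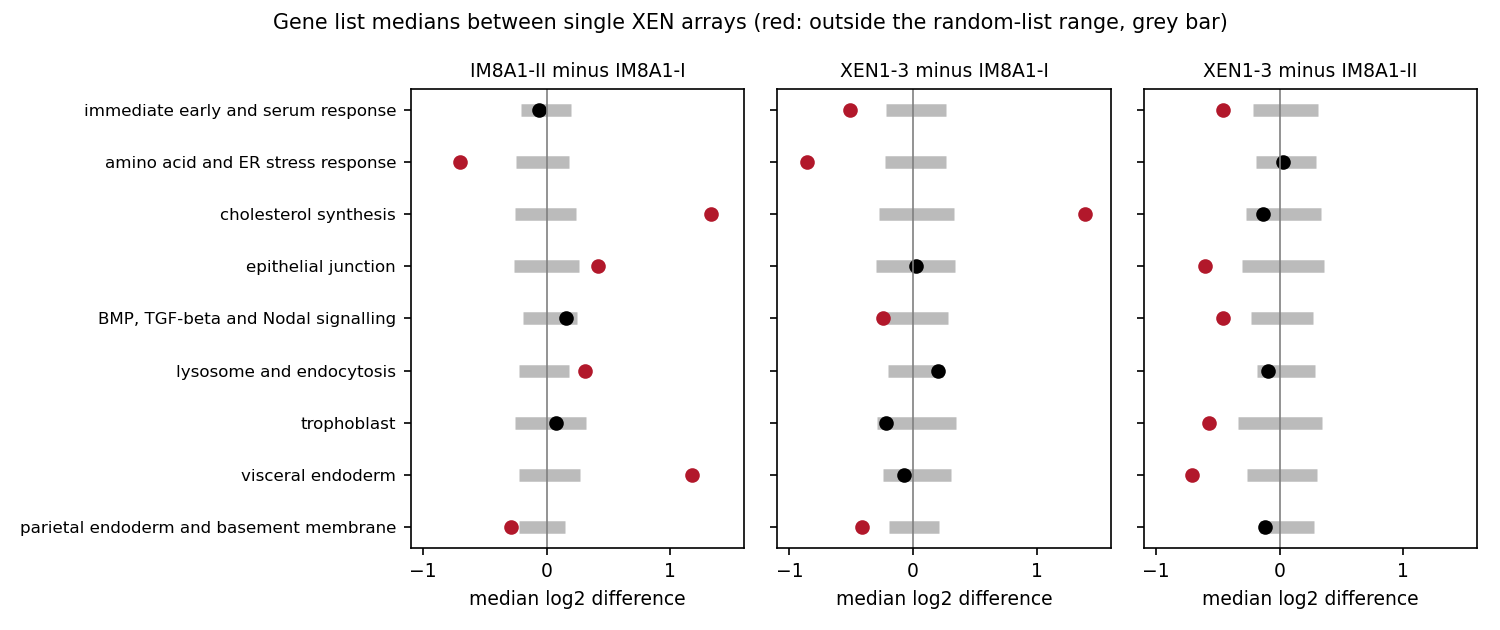
Median log2 difference (points) of the gene lists that lay outside the random-list range in at least 1 of the 3 pairs of XEN arrays, with the range of 10000 matched random lists, less 2.5% at each end, as grey bars and points outside them in red. Cholesterol synthesis genes lie at 1.33 and 1.39 in the pairs with IM8A1-I and at -0.14 between XEN1-3 and IM8A1-II.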

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

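The differences in this part were not tested, since each rests on single arrays or lies outside the tested probe sets. Fabp3 moved in opposite directions in the XEN lines relative to ES (711 units): it was 1.64 higher in log2 on average in the IM8A1 arrays (2497 and 2001 units) and had a log2 difference of -4.73 in XEN1-3, where it was under the background limit (16.6 units), so that the size is not measured. Mdfic did the same, 2.07 higher in the IM8A1 arrays (222 and 142 units, against 34.2 in ES) and a difference of -1.58 in XEN1-3 (4.5 units, under the limit). The ES value is close to the limit of 27.3, so the opposite direction of Mdfic rests on values near background. Among control probe sets that the comparisons left out, the one for the mouse B1 repeat differed between the groups, with 1695 units in ES against 431, 540 and 616 in IM8A1-I, IM8A1-II and XEN1-3, a mean log2 difference of -1.68.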

How the results depend on the processing

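No paired analysis was possible because the ES group is 1 array. All alternatives were planned. Of the 912 calls, 912 were shared with the deposited scale, 852 with quantile normalization, 858 with median scaling, 625 with each XEN line counted once (348 higher and 319 lower), 626 without a filter and 475 with values raised to the background limit. With that floor 240 probe sets were higher (main count 479) and 536 lower, so that the share of higher calls was 30.9% against 52.5%, and the prior degrees of freedom fell to 0.917. Leaving out each XEN array gave 185 to 778 higher and 181 to 710 lower. All have fewer samples, and the high ends, without XEN1-3, rest on arrays of 1 line, which lay closer together than the lines did. Of 107 genes named in this comparison 79 passed the threshold and 51 passed under all alternatives. Without IM8A1-I 18 of the 79 were lost, without IM8A1-II 14 and without XEN1-3 0, and 21 with the floor. Of the 9 lists called, 0 were called with an estimated correlation, a test with so few degrees of freedom that little could pass. Cholesterol synthesis, glycolysis, FGF and DNA methylation lists, uncalled in the main test, were called under some alternatives, though not with an estimated correlation. Each of the lists whose test changed direction was uncalled throughout. Direction here is the sign of camera's statistic, which averages over members, so it need not match the sign of the median. It turned from up to down for cyclin D and CDK inhibitors, whose medians stayed positive, and from down to up for the others. The medians of these lists were, for cyclin D and CDK inhibitors, 0.45 with the stricter filter, 0.15 with the mean of a gene's probe sets, 0.15 without a filter, 0.10 with an offset of the 50th percentile and 0.079 with quantile normalization. With the stricter filter they were 0.0018 for imprinted genes, 0.78 for interferon and 0.57 for trophoblast, and for BMP, TGF-beta and Nodal -0.07 without XEN1-3 (from -0.48 to 0.10 with each XEN array left out), and the cause was not tested. Between IM8A1-II and IM8A1-I, 301 higher and 212 lower probe sets became 80 and 40 at 3-fold, 182 and 119 with the stricter filter, 108 and 64 with an offset of the 50th percentile and 465 and 360 with one of the 5th. Between XEN1-3 and IM8A1-I, 393 higher and 389 lower became 99 and 147 at 3-fold, 125 and 177 with an offset of the 50th percentile, and 249 higher with the stricter filter. A larger offset shrinks differences of dim probe sets by construction, and a stricter filter tests fewer. Foxa2 in IM8A1-II against IM8A1-I changed sign with median scaling (-0.073). Signal over background limits dim genes, for which only bounds on the fold are given.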

Other observations

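The tests of X-linked genes, of Eif2s3x and of the medium were chosen only after the results were seen. The comparison of chromosomes was not among those fixed beforehand. The remaining pair of XEN arrays, XEN1-3 against IM8A1-II, differs in line, strain, passage and culture together. Visceral endoderm genes had a median of -0.71 in XEN1-3 relative to IM8A1-II (8 of 19 at least 2-fold lower, 0 higher), epithelial junction genes -0.60, trophoblast genes -0.57, immediate early genes -0.46 and BMP, TGF-beta and Nodal genes -0.46, each outside the range of random lists. Apoe, the apolipoprotein, was at 11.6 units in XEN1-3, 888 in IM8A1-II and 1836 in ES, and Rbp4 at 130, 2671 and 4.70. The imprinted RNA Meg3 was at 315 in ES, 127 in XEN1-3, where another probe set was near the limit at 29.3, and under the background limit in both IM8A1 cultures.

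Xist, the RNA that silences an X chromosome in female cells, was at 207 and 255 units in the IM8A1 arrays and under the limit in ES and XEN1-3, while the Y-linked Eif2s3y was at 244 in ES and 145 in XEN1-3 and under the limit in both IM8A1 arrays. Signal from its X-linked copy Eif2s3x in the Eif2s3y probe set is argued against by Eif2s3x itself, which was 1.16-fold higher in XEN1-3 than in IM8A1-I. A pair of active X chromosomes in IM8A1 is argued against by the X-linked genes, whose median relative to autosomal genes was -0.11 in IM8A1-I minus XEN1-3 (bootstrap interval -0.22 to -0.03). The interval treats the genes of 1 pair of arrays as independent and leaves out the spread between chromosomes. In that pair the median of chromosome 16 was -0.35 in XEN1-3 minus IM8A1-I. A difference in sex chromosomes between the lines may account for the pattern as a hypothesis, but 0 of 8 further Y-linked probe sets showed it and all 8 were under the limit on all arrays, so nothing here decides it.

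Stress genes were highest and cholesterol synthesis genes lowest in IM8A1-I, with medians over ES of 1.80 and -2.0, against 0.49 and -0.55 in IM8A1-II and 0.45 and -0.33 in XEN1-3. An effect of the 70% EMFI-CM medium shared by both XEN lines is argued against by XEN1-3, which had the same medium and medians of -0.85 and 1.39 relative to IM8A1-I, but a response of the IM8A1 line to it stays open. Of the 4 scalings tried, only quantile normalization could have moved these lists in opposite directions. It left a smallest median of 0.697 in size in IM8A1-II or XEN1-3 minus IM8A1-I. To that extent array scaling is argued against too. A state of that culture, such as nutrient supply or density, could be the source, and so could handling of that sample, and with 1 array neither was tested.

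Genes of chromosome 16 were lower in XEN1-3 than in both IM8A1 arrays (medians of -0.35 and -0.32), as were those of chromosome 4 (-0.21 and -0.25), and against IM8A1-I 83.5% and 69.9% of their genes lay below the median of all genes. A few strong genes would not move such medians, of which these shares are no independent test, and array scaling is argued against by shifts, relative to the median of all genes, that stayed at -0.35 and -0.25 or beyond under 4 scalings, of which only quantile normalization could have removed them. All 3 parts of each chromosome by gene order were lower against both IM8A1 arrays, the nearest to 0 at -0.28 and -0.13, which is what a copy number difference between the lines would need. Chromosomes 16 and 4 had the lowest medians of the 20 against both IM8A1 arrays. No other chromosome was cut into parts, so the parts are no independent test. As a hypothesis, chromosome 16 may differ in IM8A1, whose IM8A1-I array was 0.38 above ES, and chromosome 4 in XEN1-3, which was at -0.34 against ES (IM8A1-I at -0.10), but chromosome 19 was as far from ES, at 0.36 in XEN1-3 and 0.22 in IM8A1-I. Random lists put 15 of 20 chromosomes outside their range in XEN1-3 minus IM8A1-I, and chromosomes 1, 8, 11 and 12 were also lower against both IM8A1 arrays, so they understate the spread between chromosomes, and strain differences stay open.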
